A study of Mus musculus with 9 samples.

How the data were processed

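The series measured RNA recovered by immunoprecipitation (RIP-seq) of SAFB1, a nuclear RNA-binding protein of the scaffold attachment factor B family, from sonicated lysates of mouse embryonic stem cells. Per the labels, the cells were of a male CAST/B6 Rosa26-RMCE line, and all were induced with doxycycline for 3 days. The 9 libraries fall into 5 groups by antibody and genotype. The groups were SAFB1 antibody in wild-type cells (3 libraries, from the parent line and a pair of clones), IgG in wild-type cells (2), SAFB1 antibody in Safb and Safb2 double-knockout clones (2), FLAG antibody in double-knockout cells with an eGFP plasmid (1) and FLAG antibody in double-knockout cells with a SAFB1 plasmid (1). The genotype label of the last library reads wild type while its title names a double-knockout clone, and the title was followed. Per the labels' protocols, libraries were made after removal of ribosomal RNA, with a spike-in of synthetic ERCC RNAs, and sequenced on a NextSeq 500.

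The deposited data used here are 1 list of 30998 peaks for the whole series, with 6 columns and no header: chromosome, start, end, name, score and strand. The score that the authors deposited is 500 in every peak, so it carries no information and was not used. The list holds no column of reads or signal per library. The submitters' processing notes name the mouse build mm10, STAR (an aligner), Subread and featureCounts (a read counter), with no versions. How peaks were called, whether libraries were pooled, and which comparison decided the peaks that were kept are not given in the sources used here. The peak names carry a wild-type SAFB label, the strand and a number, and no library. The numbers rise along every chromosome and strand and reach 173296 on the plus strand and 167023 on the minus strand. If each number stands for 1 call, at least 340319 calls were made and at most 9.11% of them were kept.

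The planned tests of SAFB1 against IgG in wild-type cells, of wild type against double knockout, and of FLAG libraries with and without SAFB1 need values per library and were not run. Library depth is unknown from this list, so the precision that depth gives to a single peak cannot be stated. All results describe positions in this single list, without replicates. Confidence intervals of shares are 95% Wilson intervals, which treat peaks as independent and cover counting error only.

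Peak starts were taken as counted from 0, as in the BED format, which no source states. A shift of 1 base is the most this could change. Genes, exons, coding sequences and untranslated regions came from GENCODE M21, an annotation of GRCm38, the assembly that mm10 names (55450 genes). Each peak was placed by its midpoint, in the order exon of a gene on the same strand (sense), intron of a sense gene, antisense of a gene, outside genes. Exons of all transcripts were used. Peaks were counted for every sense gene covering the midpoint, and 792 peaks lay in more than 1 such gene. For tests within genes, each sense peak had 1 gene, protein-coding before others and shorter before longer. Each such peak was then placed 1000 times at random inside its own gene, wholly within the gene and with its own width, and observed shares were set against the lowest and highest of those placements. These placements measure chance of position, and not the spread between libraries.

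Before the data were examined, 19 gene lists with 462 entries were fixed, as were the tests, the first set of alternatives and the rule for naming genes. All list entries were found in the annotation. Each list was compared with 10000 random lists of equal size, matched on gene length in 20 bins, drawn from protein-coding genes and genes of the lists. Lists were not matched on expression, since no expression values were used. The named genes are the 20 with most sense peaks, the 10 with most peaks per kb among genes with at least 5 peaks, the 10 with most exonic peaks, the 10 non-coding genes with most peaks, Safb, Safb2 and Sltm, and up to 4 members of each list with most peaks. The 20 genes with most peaks end at a tie, which was broken by gene identifier, and other tied genes are named with the last of their list. Some genes that this rule covers are not reported here. Genes named outside this rule are marked as chosen after their values were seen. Some alternative settings and the tests on the 20 genes with most peaks and on Safb and Safb2 were chosen after the data were seen, and an earlier shuffle of the shares of calls kept in these genes was replaced, with its value given with the other observations. The relation of peaks to gene length is Spearman's rho across genes, with an interval from 200 bootstrap draws, and genes are not independent replicates.

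Sequence was read from the GENCODE M21 transcripts, so only exonic peaks entered (2840 of 3762). For each peak 1 transcript with its midpoint in an exon was taken, the one holding most of the peak's bases, and retained-intron transcripts only where no other did. A peak entered if at least 50 of its bases lay in that transcript and the transcript was at least 2 times as long as those bases. Each was compared with 100 windows of equal length at random positions of the same transcript (20 windows for hexamers), with intervals from 1000 bootstrap draws of genes. Hexamers with an expected count of at least 50 were ranked. Sequence of introns, repeat-masked bases and windows 1 to 5 kb away in the genome were not analysed here.

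The share of calls kept in a gene is the number of kept peaks after the first, divided by the span of peak numbers between the first and last kept peak of that gene. It leaves out calls beyond those peaks. Calls per kb are that span of peak numbers divided by the distance between the midpoints of those peaks, and not by gene length.

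On simulated peaks, the placement test returned a ratio of 1.01 where the true ratio was 1 and 1.97 where it was 1.97 (5000 peaks, 2795 genes). Of 100 random gene lists 4 fell outside the range of random lists, and of 100 lists with 2 times the share of genes with peaks 73 were found above it (21951 genes). These simulated lists were all of 1 size and were compared with fewer random lists than the lists reported. The excess was built in regardless of gene length. The 73 therefore does not tell how often an excess in lists of other sizes would be found. The purine comparison returned -0.03 percentage points for random windows and 2.84 where 2.82 had been built in (1000 windows, 953 genes). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.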

Results

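SAFB1 binds RNA in the nucleus, and the series asked which RNAs it associates with in mouse embryonic stem cells. RNA was recovered with a SAFB1 antibody from wild-type cells (3 libraries) and from Safb and Safb2 double-knockout cells (2), with IgG from wild-type cells (2), and with a FLAG antibody from double-knockout cells carrying an eGFP plasmid (1) or a SAFB1 plasmid (1). What was analysed is the authors' single list of 30998 stranded peaks, which gives positions and no read counts. Differences between antibodies or genotypes could therefore not be measured, the depth behind each peak is unknown, and no result has replicates. The list describes where SAFB peaks lay in the transcriptome. It held 15997 peaks on the plus strand and 15001 on the minus strand, with a median width of 596 bases (quartiles 290 and 1100, range 74 to 5062), and covered 23.8 Mb in all. Peaks of the same strand were at least 305 bases apart, with a median gap of 17636.5 bases.

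Most SAFB peaks lay within genes on the transcribed strand, and mainly in introns. Introns of sense genes held 16905 peaks (54.5%, 95% Wilson interval 54.0 to 55.1) and their exons 3762 (12.1%, 11.8 to 12.5). A further 4039 peaks (13.0%, 12.7 to 13.4) were antisense to a gene and 6292 (20.3%, 19.9 to 20.7) lay outside annotated genes. At positions with genes on 1 strand only, 82.4% of peaks (18876 of 22915, interval 81.9 to 82.9) were on the strand of the gene. Of the exonic peaks, 1532 lay in coding sequence (40.7%), 736 in 3' untranslated regions (19.6%), 123 in 5' untranslated regions (3.27%) and 1371 in other exons (36.4%). These other exons include exons that protein-coding genes have in transcripts without a coding sequence. Exonic peaks had a median width of 775.5 bases, intronic peaks 631, peaks outside genes 504.5 and antisense peaks 480. Intervals cover counting error only.

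**Figure D1:**
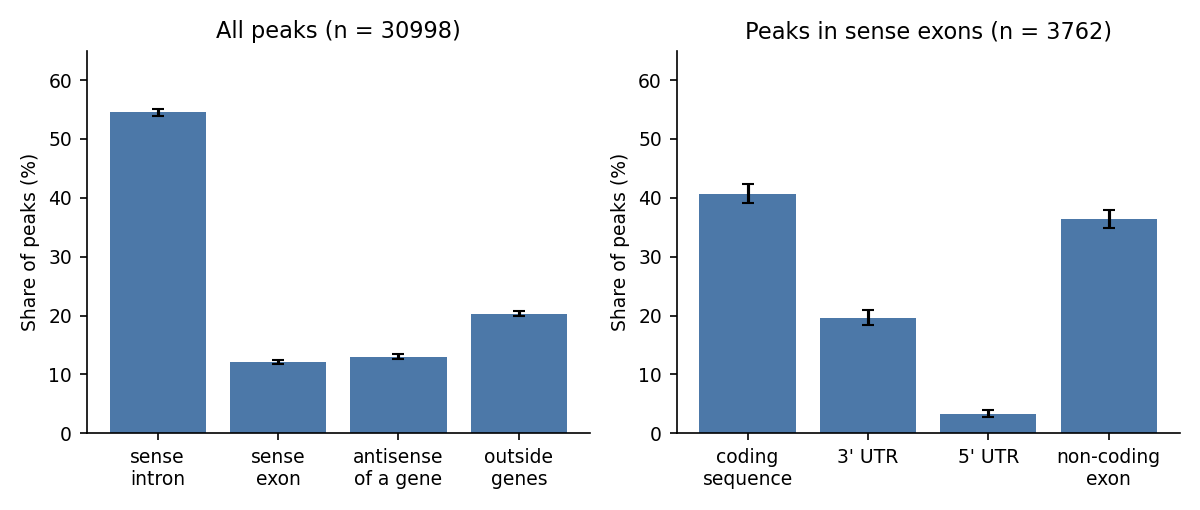
Share of peaks in percent by location relative to GENCODE M21 genes, for all 30998 peaks (left) and for the 3762 peaks in sense exons (right), with 95% Wilson intervals as error bars. Sense introns held 54.5% of all peaks, and coding sequence 40.7% of exonic peaks.

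Although introns held most peaks, exons held more than their length would give. Each sense peak was placed at random in its own gene to ask whether peaks follow the lengths of introns and exons. Exons of the assigned gene held 16.8% of the 20667 sense peaks, against a mean of 10.3% in 1000 placements (lowest 9.82%, highest 10.9%), a ratio of 1.63. In protein-coding genes the exonic share was 15.0% against 8.82% (ratio 1.70), and in long non-coding genes 27.0% against 16.5% (ratio 1.63), both above every placement. Placements kept whole peaks inside the gene. With midpoints placed anywhere in the gene, a setting chosen after seeing the data, the placed mean was 11.2% and the ratio 1.50. That setting was run over all sense peaks and not by kind of gene. RNA abundance of exons and introns was not used here, so the ratio is relative to length alone.

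Peaks spread over the whole gene body, with a median distance of 54.3 kb from the gene start (quartiles 16.3 and 143). The first 10% of the gene held 8.54% of peaks, at the lower end of random placements (8.42 to 9.81%, mean 9.18%), of which 1 of 1000 was as low. The last 10% held 10.95%, above every placement (highest 9.83%), a ratio of 1.19. Long non-coding genes had 12.5% of their peaks in the first 10%, above every placement (highest 9.96%), a ratio of 1.64, and 11.7% in the last 10%, also above every placement (highest 9.82%), a ratio of 1.52. Placements kept whole peaks inside the gene, while an observed peak needed only its midpoint there. Both ends of short genes were thus emptied in placements, to means of 7.66% and 7.69% in long non-coding genes, which raises these ratios. With midpoints placed anywhere, run over all peaks and not by kind of gene, the mean was 10.0% at each end and the ratios 0.853 and 1.10. In protein-coding genes the first 10% held 8.25%, below every placement (lowest 8.60%). The result for the first 10% depended on the setting: the ratio was 0.930 over all peaks, 1.11 with each gene counted once and 0.908 in genes of at least 10 kb, both of the latter beyond all placements. With each gene counted once, the observed share was 9.14% against a placed mean of 8.22%, which the emptied ends of short genes lower. For intronic peaks in genes of at least 10 kb, placed in introns alone in a setting chosen after seeing the data, the last 10% had a ratio of 1.03, inside the placements, and the first 10% a ratio of 0.877, below all of them.

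**Figure D2:**
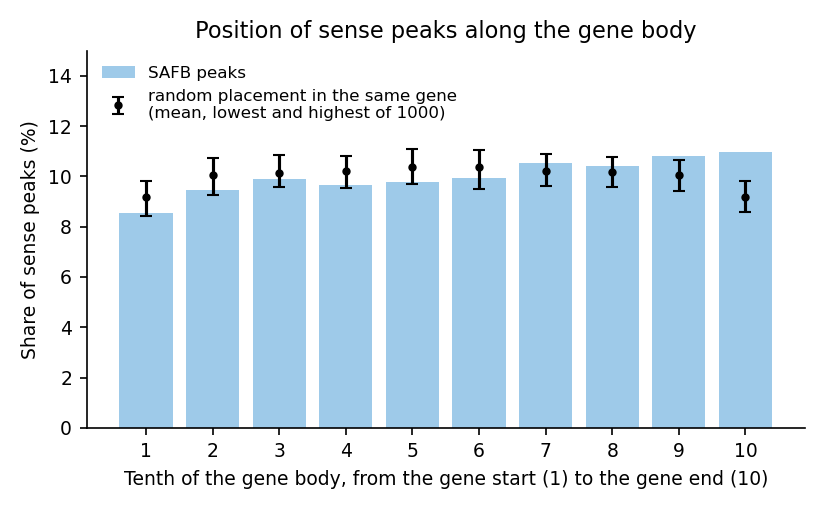
Share of the 20667 sense peaks in percent (bars) in each of 10 equal parts of the gene body, from gene start to gene end, with the mean (points) and the lowest and highest (whiskers) of 1000 random placements in the same genes. The part at the gene end, with 10.95% of peaks, lies above all placements.

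The transcripts with most SAFB peaks came from long genes. Grip1, a scaffold protein of glutamate receptors (chromosome 10, 119453830 to 120087261, mm10, plus strand), held 167 sense peaks, of which 164 were intronic. Dpp6, an auxiliary subunit of potassium channels (chromosome 5, 26817203 to 27727505), held 158, and Pde4d, a cAMP phosphodiesterase (chromosome 13, 108449948 to 109953461), held 151. They were followed by Hs6st3 (91), Tenm4 and Gpc6 (72 each), Rora (64), Aff3 and Gm20388 (56 each), Ank2 (54), the guidance cue gene Ntn1 (53), Xkr4 and Shisa6 (52 each), Ctnnd2 (48), Sulf1 (47), Lpp and Atrnl1 (46 each), Wwox and Dab1 (45 each) and Tenm3 (43, a count shared by Magi2 and 2610307P16Rik). Gm20388 is annotated over 4435 kb, and 36 of its 56 peaks also lay in another gene of the same strand. The same held for 5 peaks each of Ank2 and Xkr4 and for 1 peak each of Grip1, Dpp6, Ntn1 and Tenm3.

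In all, 7093 genes held at least 1 sense peak, 3728 of them exactly 1 (52.6%) and 411 at least 10. The 100 genes with most peaks accounted for 17.3% of all pairs of peak and gene. Among protein-coding genes 5750 of 21951 had a peak (26.2%, interval 25.6 to 26.8), among long non-coding genes 827 of 10155 (8.14%, 7.63 to 8.69) and among pseudogenes 346 of 13523 (2.56%, 2.31 to 2.84). Leaving out peaks in more than 1 sense gene gave 6410 genes.

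Longer genes held more peaks. Across the 7093 genes with a peak, Spearman's rho between number of peaks and gene length was 0.583 (bootstrap interval 0.568 to 0.598), a description across genes, which are not independent replicates. The share of protein-coding genes with a peak was 6.05% (5.54 to 6.60) below 10 kb, 21.3% (20.4 to 22.3) from 10 to 30 kb, 42.4% (41.1 to 43.8) from 30 to 100 kb, 68.1% (66.0 to 70.1) from 100 to 300 kb and 68.6% (64.7 to 72.3) above 300 kb. Relative to length the density varied less, from 14.6 peaks per Mb in protein-coding genes below 10 kb to 22.9 from 100 to 300 kb.

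By density, the transcripts of the knocked-out genes themselves stood near the top. Safb (ENSMUSG00000071054.12, chromosome 17, 56584825 to 56606294, plus strand) held 13 peaks, 9 of them exonic, or 0.605 per kb, the highest density among the 1053 genes with at least 5 peaks. Safb2 (ENSMUSG00000042625.16, 56560965 to 56584585, minus strand), which lies head to head with Safb at a distance of 239 bases, held 10 peaks, 9 of them exonic, or 0.423 per kb, and ranked 5. Peaks covered 29.0% of Safb and 21.9% of Safb2. The related gene Sltm held 1 exonic peak. Every call between the first and last peak of Safb and of Safb2 was kept in the list (100%). In genes with at least 5 peaks and a number of calls within 2 of theirs, a comparison chosen after seeing the data, the highest share was 80% for Safb (75 genes) and 87.5% for Safb2 (65 genes). Other genes of high density were Platr4 (0.545 per kb), 4933412E12Rik (0.444), Lyar (0.434), 5730419F03Rik (0.414), Gm11520 (0.355), Gm48293 (0.325), Nop14 (0.324) and 9330185C12Rik (0.302). Of these, Lyar, which encodes a nucleolar protein, had 5 of 6 peaks in exons, and Nop14, a ribosome biogenesis gene, 6 of 7.

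**Figure D3:**
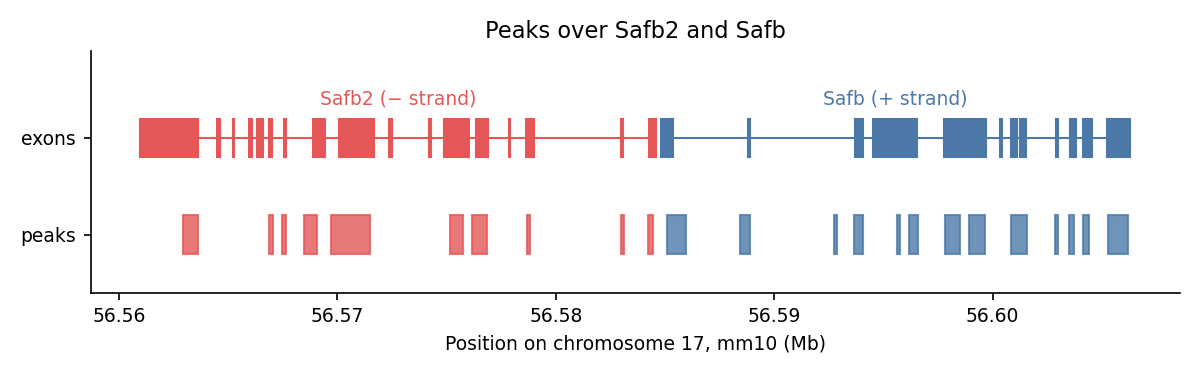
Map of Safb2 and Safb on chromosome 17 (mm10, position in Mb), with annotated exons of all transcripts above and the deposited peaks of the same strand below. Safb2 held 10 peaks and Safb 13, and 9 in each gene had their midpoint in an exon.

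The transcript with most exonic peaks was Kcnq1ot1, an imprinted non-coding RNA (chromosome 7, 143203458 to 143296549, minus strand), with 19 peaks, all exonic. Exonic here means within an annotated exon of any transcript, which does not tell spliced from unspliced RNA. After Safb and Safb2 (9 each) came Cald1 (8 of 28 peaks), Bicd1 (7 of 14), Ktn1 and Dido1 (7 of 8 each), Magi2 (6 of 43, 1 of them in another gene as well), Mipol1 (6 of 34) and Eif4g3 (6 of 16). Smc6, Nop14, Rock1, Esf1 and Top1 also held 6.

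Long non-coding RNAs that act in the nucleus or at imprinted loci carried SAFB peaks more often than genes of similar length. Of the 30 genes in this list 22 had a peak, while random lists of matched length had a median of 10 (middle 95% from 6 to 14), and none of the 10000 random lists had as many. Airn, the imprinted antisense transcript of Igf2r (chromosome 17, 12741311 to 12860136, plus strand), held 21 peaks, all in introns as annotated. Kcnq1ot1 held 19, Pvt1 14 and Dleu2 8, of which 4 also lay in another gene. Drawn from non-coding genes alone, random lists had a median of 4 (1 to 8). Neither comparison was matched on expression, so the excess is relative to gene length alone. The count fell inside the random range, at 11 of 30 (4 to 12), once peaks were left out of genes where at least 40% of calls had been kept, a setting chosen after seeing the data. That share is computed from the kept peaks, so the setting takes out genes because their peaks follow each other closely. It took out Airn (64.5%), Kcnq1ot1 (41.9%) and genes with only 2 peaks, such as Meg3 and Tsix (100% each). It therefore cannot decide whether the excess of this list holds. Over all long non-coding genes, those with most peaks were 2610307P16Rik (43), Gm14005 (23), 9330185C12Rik (22), Airn (21), AC174800.1 (21, with 15 in another gene as well), Kcnq1ot1 (19), Pvt1 and 6030443J06Rik (14 each), 2610037D02Rik (13), and Gm2164 and Gm38825 (12 each). 6030443J06Rik and 2610037D02Rik each shared 1 peak with another gene.

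By number of genes with a peak, the other 18 lists lay within the range of random lists of matched length. Among gene groups for RNA handling, 10 of 25 SR proteins had a peak (random median 6, range 2 to 10), with 10 peaks in Rsrc1, 6 in Pnisr and 4 in Luc7l3, and 6 of 32 hnRNPs and nuclear matrix proteins (7, 3 to 12), with 4 in Khdrbs1 and 2 each in Ptbp3 and Raly, those of Raly lying in another gene as well. RNA polymerase II and elongation factors had 12 of 31 (11, 6 to 15), led by Rtf1 (7), Cdk13 (6), Ell2 (3) and Ctr9 (2). The SAFB family had 3 of 3 (1, 0 to 3), so its count could not lie above that range. With only peaks at least as wide as the median it lay above the random range (0 to 2). Without genes where at least 40% of calls were kept, a setting chosen after seeing the data, it had 1 of 3 (0 to 2). Its median density, 0.423 per kb, was that of Safb2 and stood at percentile 100 of random lists, while Sltm had 0.0202 per kb. Hosts of small nucleolar RNAs had 4 of 24 (3, 1 to 7), with 4 peaks each in Cwc22 and Taf1d, 2 in Epb41l2 and 1 in Nop58.

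Ribosomal proteins and translation and glycolysis genes, with median lengths of 3.79 and 6.74 kb, carried few peaks, as did random genes of their length. Ribosomal proteins had 2 of 47 (random median 3, range 0 to 7), Rpl11 and Rpl26 with 1 peak each, and translation and glycolysis genes 2 of 25 (3, 0 to 6), Eif4g2 and Hsp90aa1 with 1 each. Both ranges begin at 0, so neither count could lie below its range. Pluripotency factors had 6 of 30 (7, 3 to 11), with 2 peaks each in Esrrb and Tet2 and 1 each in Klf5, Tet1, Tfcp2l1 and Zfp42. The lists that follow hold longer genes, with median lengths from 45.5 kb (X-linked genes of general use) to 77.9 kb (chromatin regulators). Chromatin regulators had 18 of 38 (20, 14 to 25), led by Arid1b (10), Chd7 (7), Crebbp (5) and Ehmt1 (3, with 1 in another gene as well). DNA replication and repair genes had 11 of 30 (12, 7 to 17), led by Rad51b (16), Polq and Top1 (7 each) and Pola1 (6). Imprinted protein-coding genes had 14 of 25 (10, 6 to 15), with 15 peaks in Trappc9, 10 in Gnas, 9 in Grb10 and 6 in Plagl1. X-linked genes of general use had 12 of 22 (10, 6 to 14), led by Pola1 (6), Mbtps2 and Stag2 (4 each) and Smc1a (3), with 1 of the peaks of Mbtps2 in another gene as well.

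Markers of most other cell types did not stand apart either. Liver genes had 0 of 15 (random median 3, range 0 to 5), so their count could not lie below that range. As few were found in 4.13% of the random lists. Blood cell genes had 3 of 15 (4, 2 to 7), namely Fli1 and Ikzf1 with 3 peaks each and Runx3 with 1. Fibroblast markers had 5 of 18 (7, 3 to 11), with 2 each in Fbn1 and Pdgfrb. Striated muscle genes had 5 of 15 (6, 3 to 9), with 15 peaks in Ryr2, of which 2 lay in another gene as well, and 2 each in Ryr1 and Ttn. Primitive endoderm markers had 8 of 15 (6, 3 to 10), led by Col4a2 (11), Lama1 (5), Col4a1 (4), and Dab2 and Lamb1 (3 each). Long neuronal genes had 12 of 22 (15, 11 to 19). Their median density, 0.000638 per kb against a random median of 0.0111, stood at percentile 1.73 of random lists. Length was matched only in bins, however, and the median length of this list was 1101 kb, so its random lists may hold shorter genes. Among protein-coding genes, density was 22.9 peaks per Mb from 100 to 300 kb and 16.1 above 300 kb. Whether the low density reflects imperfect matching was not tested. Dpp6 held 158 of the 192 peaks of that list, Ctnna2 7 and Erbb4 5. With at least 2 peaks required, 6 of the 22 long neuronal genes counted, below the random range (9 to 18). With a peak at least as wide as the median required, 6 counted, also below it (9 to 18). The limit of matching in bins holds for these counts too.

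**Figure D4:**
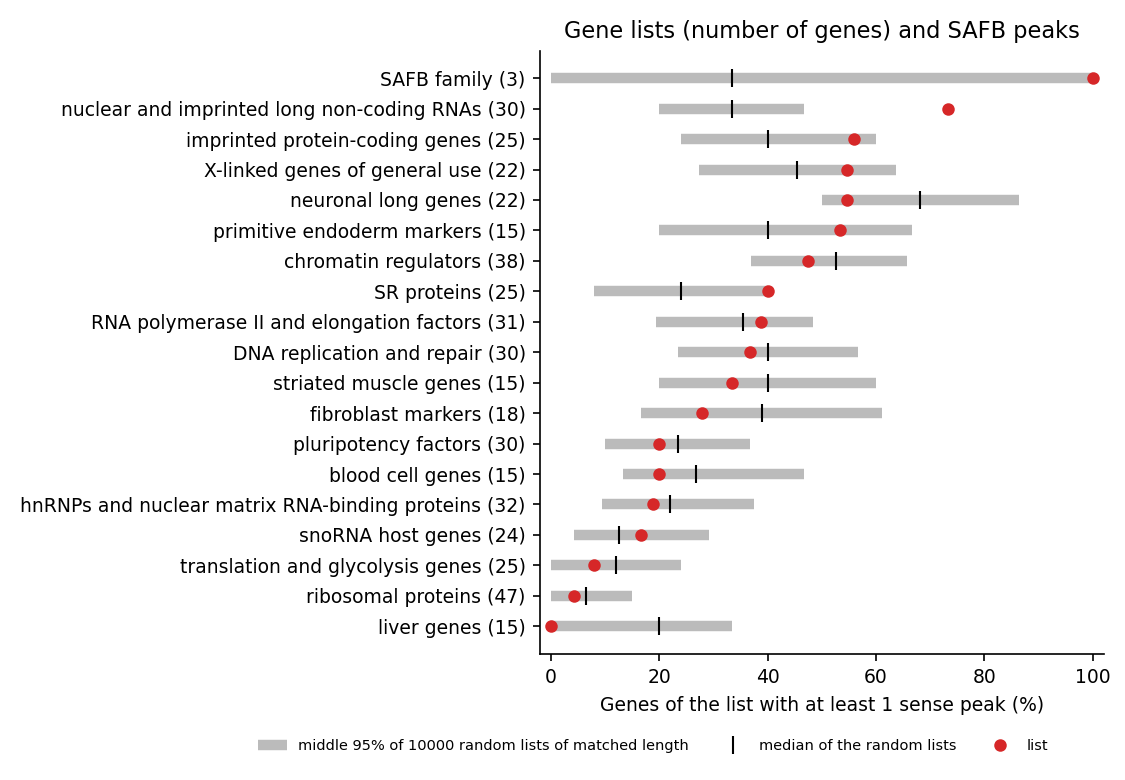
Percent of genes with at least 1 sense peak in each of 19 gene lists (red points, number of genes in brackets), with the median (tick) and the middle 95% (grey bar) of 10000 random lists matched on gene length. Nuclear and imprinted long non-coding RNAs, with 22 of 30 genes, lie above their range.

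The X chromosome, present in 1 copy in these male cells, had a lower density of peaks than the autosomes together. It held 756 sense peaks, or 14.4 per Mb of gene body, against 16.4 per Mb on the autosomes, a ratio of 0.876 (interval 0.814 to 0.942, counting error only). Single autosomes ranged from 12.2 per Mb on chromosome 6 to 20.7 on chromosome 18, so the X lay within their spread, with 1 autosome below it. The Y chromosome held 11 peaks.

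Sequence under exonic peaks was richer in purines than random windows of the same transcripts, which could overlap the peak. This comparison addresses the described preference of SAFB proteins for purine-rich RNA. Over 2840 exonic peaks in 2108 genes, A and G made up 54.7% of bases, against 52.1% in matched windows of the same transcripts, a difference of 2.60 percentage points (bootstrap interval over genes 2.36 to 2.83). It was smaller, at 1.45 (1.20 to 1.69), for the 1362 peaks wholly inside 1 exon and, at 1.64 (1.33 to 1.97), for the 1069 peaks compared within coding sequence, both settings chosen after seeing the data. The peak exceeded the mean of its matched windows in 69.8% of cases. Among 4053 hexamers, the top 3 were AGAAGA (ratio 1.49, interval 1.41 to 1.56), GAAGAA (1.48, 1.40 to 1.56) and AAGAAG (1.47, 1.39 to 1.55), and 63 of the 64 hexamers made of purines alone had a ratio above 1. The lowest ratios belonged to TATATA (0.459, 0.387 to 0.544) and ATATAT (0.503, 0.422 to 0.587). Hexamers were not compared within coding sequence alone, so differences between coding and untranslated sequence may enter these ratios. GC content was 0.720 percentage points higher in peaks than in matched windows (0.487 to 0.945) but -0.365 (-0.660 to -0.0634) within coding sequence.

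**Figure D5:**
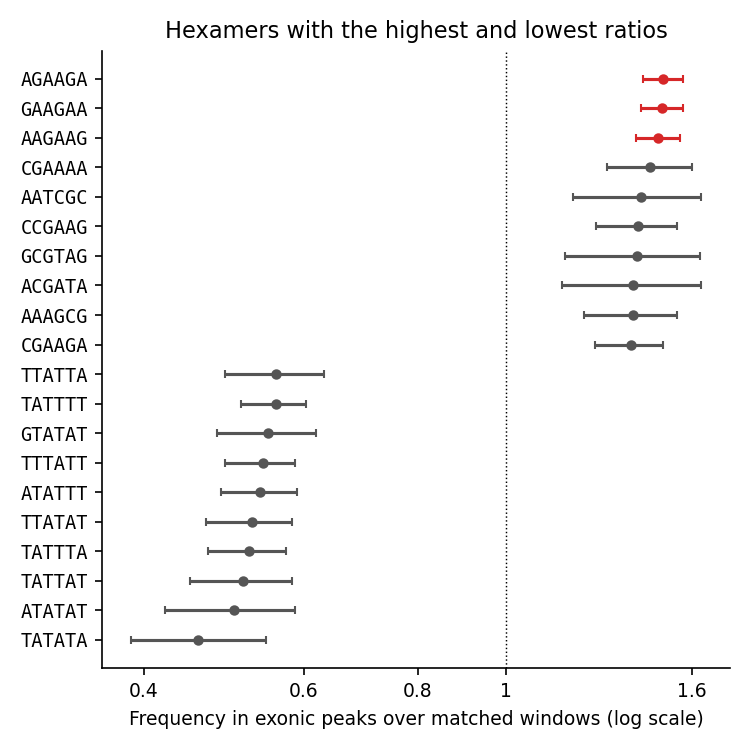
Ratio of hexamer frequency in 2840 exonic peaks over matched windows of the same transcripts (log scale) for the 10 highest and 10 lowest of 4053 hexamers, with 95% intervals from 1000 bootstrap draws of genes. Red points are hexamers of purines only, led by AGAAGA at 1.49.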

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

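Of 43 alternative settings 23 left the result on its side of the test, within its error or, for the number of genes with a peak (5284 to 7093), within 1.5 times, and those named here did otherwise; settings on shares of calls kept, on placement anywhere, on protein-coding genes and intronic peaks in placement, on single exons and coding sequence, and without the genes with most peaks were chosen after seeing the data. The share of peaks in sense introns (54.5%) was 49.4% by any overlap with a gene, where 1 exonic base makes a peak exonic by construction. With protein-coding genes only it was 51.9%, where introns of other genes no longer count by construction. It was 55.1% by most of the peak, 56.9% for peaks at least as wide as the median and 56.8% with 1 transcript per gene, where fewer bases count as exon by construction. Spearman's rho was 0.486 over all protein-coding genes. The ratio for the first 10% of genes (0.930) turned to 1.11 with each gene counted once, 1.05 in genes with at most 5 peaks and 1.01 for the wider peaks, and left the placement range at 0.908 in genes of at least 10 kb, 0.853 with midpoints placed anywhere, 0.883 in protein-coding genes, and 0.877 for intronic peaks in genes of at least 10 kb placed in introns (0.884 placed in exons too, which lowers parts rich in exons by construction). In this last pair the ratio for the last 10% (1.19) was 1.03, inside the placements, and 0.846. Elsewhere it stayed above all placements, at 1.10 to 1.46, highest with each gene counted once. Except with midpoints placed anywhere, placements empty the ends of short genes, which raises the ratios at both ends by construction. Lists outside the random range numbered 1, against 2 with at least 2 peaks, 3 with the wider peaks and 0 without genes where at least 40% of calls were kept. That last setting takes out genes with close kept peaks by construction. Drawing random lists from genes with a peak gave 18 by construction. X over autosomes was 0.744 by peaks per gene. The GC difference reversed to -0.365 in coding sequence. For the others the cause was not tested.

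The exon ratio (1.50 to 1.70) and the purine difference (1.45 in peaks within 1 exon to 2.92 in central bases) kept their direction and side in every setting run. Merging peaks within 100 bases changed nothing, since no peaks were that close. No paired analysis was possible because the list has no values per library. For the same reason the count tests, other scalings and leaving out replicates were not run, nor were intronic, repeat-masked and 1 to 5 kb sequence windows. Depth limits which peaks could be called and is unknown.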

Other observations

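Of the tests reported here, the 3 on the genes with most peaks and the 2 on Safb and Safb2 were chosen after the result was seen, and the others before. The 2 replaced versions written before, with the same outcome, that set the share kept against all genes with at least 5 peaks, most of which have more calls. Of the 3, those on length and on the share kept replaced versions that did not repeat the choice of genes by their counts. The one on calls per kb does not repeat it either, its bounds were set when a first ratio was already known, and genes of similar length were added later. For the share of calls kept, shuffling over all genes with at least 5 peaks was tried first and gave 56.3% (44.0 to 70.8) against 27.6% observed, which would have argued against a higher share kept as the source of the counts. It was dropped because genes with fewer calls kept a higher share of them (Spearman's rho -0.682), so it gave long genes shares typical of genes with few calls. Genes and regions in the first paragraphs were chosen after their values were seen.

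Some genes held exonic peaks far richer in purines than random windows of their transcripts. Among genes with at least 3 exonic peaks compared, the difference was highest in Nucks1, 18.4 percentage points over 4 peaks. It was 16.2 in Ccdc34 (4 peaks), 15.3 in Pdap1 (3), 13.1 in Ccar1 (3) and 12.1 in Rbm25 (4). Other genes went the opposite way, the lowest being Sema6a with -3.43 (3) and Cep290 with -3.04 (4). The difference was -2.17 in Safb (8) and 3.62 in Safb2 (7).

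In 9 of the 1053 genes with at least 5 peaks every call between the first and last peak was kept. They were Safb (13 peaks), Safb2 (10), Nop14 (7), Glis2, Eif2d and Lyar (6 each), and Dek, Gm11520 and Gm3716 (5 each). Nop14 and Lyar are genes of the nucleolus and Dek encodes a chromatin protein.

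The largest group of peaks outside genes, with gaps of at most 20 kb, lay on the minus strand of chromosome 3 (41397160 to 41507308) around Platr4, with 37 peaks over 110 kb. A group of 23 peaks lay on the minus strand of chromosome 9 (40115169 to 40192200), and one of 21 on the plus strand of chromosome 8 (78059305 to 78133668), which began 3.83 kb past Gm29895.

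Safb and Safb2 ranked 1 and 5 by peaks per kb, and the labels name a double knockout of both. A high number of calls kept at the usual rate is argued against by the calls of Safb2 and by the share kept. Between its first and last peak Safb2 had 0.427 calls per kb (Safb 0.593). The 95th percentile by the same measure was 0.560 in genes with at least 5 peaks. In both genes 100% of calls between the first and last peak were kept, against at most 87.5% in 65 genes with a number of calls within 2 of Safb2 and 80% in 75 such genes for Safb, all with at least 5 peaks. A selection against double-knockout libraries may produce this if those cells lack these transcripts. No source used here states that selection or that loss, and Lyar and Nop14, not named as knocked out, also kept 100%. Binding of SAFB1 to the RNA of its own family stays open, as untested.

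The 20 genes with most peaks may owe their place to more than length. With all peaks shared out at random by gene length and the 20 genes chosen again, the median density was 0.0369 per kb (0.0347 to 0.0395), against 0.0954 observed. The counts of the chosen genes had the same median, 53.5, but length put them in longer genes, with a median of 1515 kb against 682 kb. More calls per kb between the first and last peak stay open. The ratio was 0.981 (bootstrap interval 0.824 to 1.16) to other genes with at least 5 peaks but 1.97 (1.46 to 2.47) to genes nearest in length with at least 2 peaks. Calls per kb of the whole gene were not compared. The share of calls kept was 27.6%, against 19.2% (13.7 to 27.5) in random sets of 20 other genes with at least 5 peaks and 28.0% (25.9 to 29.5) with shares shuffled among genes of similar numbers of calls and the top 20 chosen again, so a higher share kept cannot be told apart from the way the genes were picked, and no biological explanation was tested.

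Peaks outside annotated genes lay near genes: 46.9% were within 10 kb downstream of a gene end on the same strand, against 11.1% of random positions outside genes (10.5 to 12.0 over 20 sets). Downstream peaks outnumbered upstream ones by 2.34 times (interval 2.19 to 2.50), as transcription running past gene ends would give, though gene ends missing from the annotation could give the same. Peaks pointing away from an opposite-strand gene start were 0.978 times as many as those pointing into an opposite-strand gene end (0.907 to 1.06). That interval lies far below the 2 times set for divergent transcription as the main source, but it includes 1. The intervals of both ratios cover counting error only. They treat peaks and the counts compared as independent, though 1 peak could enter both counts of a ratio. On the divergent side lay 20.9% of peaks against 10.9% of random positions. The excess was alike on the convergent side (21.3% against 10.9%) and upstream on the same strand (20.1% against 10.9%). It therefore does not single out promoters, and a part from them stays open. No difference between groups of the design was tested.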
